A study of Mus musculus with 2 samples.

How the data were processed

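RNA was measured in cultured B-cell lymphoma cells of Eµ-Myc mice, which carry a Myc transgene driven by the immunoglobulin heavy chain enhancer and develop B-cell lymphoma. Per the labels, 1 array held RNA of a lymphoma with intact Cdk4 and 1 array RNA of a lymphoma with both copies of Cdk4 deleted, and both lymphomas came from lymph nodes. Per the labels' protocols, the cells were grown in culture medium with fetal bovine serum, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of total RNA for Affymetrix mouse expression arrays. The deposited values are signal intensities on a linear scale, 1 for each of 45101 probe sets on each array, and they were made with MAS5, per the submitters' processing notes. The version of MAS5 is not given in the sources used here. In the deposited intensities the mean after trimming 2% of the probe sets from each end was 500.003 on both arrays. The detection calls of MAS5 were not used here, so a floor of signal took their place.

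Each group held 1 array, so no replicate, standard error or p-value exists for any difference between them, and the number of arrays limits the precision of every statement. The comparison, the floor, the gene lists, the rule for the genes named in the text and the alternatives were chosen before the data were examined, except where the text says otherwise. Both arrays were rescaled to the same trimmed mean, which gave a factor of 1 for each. The floor was the median intensity over all probe sets of both arrays with the 64 control probe sets left out, which was 62.2. Intensities below the floor were set to it, and log2 was taken after that. Differences are the array labelled Cdk4 null minus the array labelled Cdk4 wild type. A gene above the floor on both arrays has a measured fold. A gene above the floor on only 1 array has a bound, written as at least that many-fold, and a gene below the floor on both has no fold.

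Probe sets were named from GEO's platform annotation, which gave 1 gene symbol for 34958 probe sets, several symbols for 932 and none for 9160. Of the probe sets with 1 symbol, 34754 had theirs in a RefSeq gene table of the mouse assembly GRCm38.p6, with 0 symbols changed by it. That table was used only for names, chromosomes and the order of genes along them. Of the probe sets of a gene, the 1 with the highest mean log2 intensity stood for the gene, which left 18193 genes. Of these, 9418 were above the floor on both arrays, 636 only on the array labelled wild type, 666 only on the array labelled null and 7473 on neither.

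Genes were counted at a difference of 2-fold or more in each direction, with bounds counted apart. The spread between probe sets of the same gene served as the measure of error. Probe sets marked a, s, x or f at the end of their name were left out of this measure. They share sequence with other transcripts, of the same gene or of other genes, and are called shared probe sets here. The SD of a log2 difference was 0.32 per probe set, over 3082 genes with a second probe set above the floor on both arrays. This covers probe set error and not the variation between cultures or tumours. Named genes were Cdk4, the 12 genes with the largest measured difference in each direction whose other probe sets above the floor had the same sign, the 5 genes with the largest bound in each direction, and the 4 members of each gene list with the largest difference. Immunoglobulin, T cell receptor and sex-linked genes and unnamed transcripts took no place among the 12 and the 5. Examples given below from a list are taken from its 4 members, and other genes are said to be chosen after their values were seen.

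The 33 gene lists covered the CDK4 kinase complex and D cyclins, CDK inhibitors, pocket proteins and E2F factors, E2F target DNA replication genes, mitosis genes, Myc targets in growth and ribosome biogenesis, Myc network factors, damage-induced arrest and apoptosis genes, regulators of damage-induced arrest, DNA damage response and repair, and the BCL2 family and caspases. Lists of cell identity covered pan-B, pro-B and pre-B, mature B, germinal centre B and plasma cell genes, MHC class I and class II genes, markers of T and NK cells, of macrophages, granulocytes and dendritic cells, of erythroid cells and of stromal and endothelial cells, and immunoglobulin, T cell receptor and sex-linked genes. The others covered NF-kB targets, interferon response, glycolysis and hypoxia, unfolded protein and amino acid stress, immediate early, cholesterol synthesis, cytosolic ribosomal protein and histone genes. The median log2 difference of each list's members above the floor on at least 1 array was given a percentile among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list below percentile 2.5 or above percentile 97.5 was called apart, and 30 lists had enough members. About 1.5 of 30 lists would stand apart by chance. Chromosomes were treated in the same way, and about 1 of 20 would stand apart by chance. Percentiles describe these 2 arrays, and the genes of a list or chromosome are not independent of one another.

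Alternatives were the deposited values without rescaling, quantile normalization and a median difference set to 0. Further ones were a floor at the 25th or 75th percentile of the signals and no floor with a pseudocount of 14.1. Others were the mean of all probe sets of a gene, leaving out shared probe sets, a threshold of 3-fold, and random lists not matched on signal. Some shared probe sets are specific to 1 gene, so a change without them need not come from signal of other genes. An alternative with the median of each chromosome set to 0 was added after the data were seen. The steps were tested on simulated data for 18193 genes with a noise SD of 0.3 in a log2 difference. In that test 96.5% of 200 genes with a simulated log2 change of 1.5 were recovered at 2-fold, and 0.031% of unchanged genes reached 2-fold. The changed genes were drawn from those well above the floor on both arrays, and the noise was the same at every signal. On the arrays themselves, paired probe sets differed by 1 or more on the log2 scale in 3.18% of genes. The simulated rates therefore do not carry over to these arrays, least of all near the floor. A simulated list of 20 genes shifted by 0.4 stood at percentile 100, and 2% of 200 unchanged lists were called apart. Calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.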

Results

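The series set 1 expression array of an Eµ-Myc B-cell lymphoma labelled Cdk4 wild type against 1 array of an Eµ-Myc B-cell lymphoma labelled Cdk4 null, to ask what loss of this cyclin-dependent kinase goes along with in lymphoma driven by Myc. Median intensities were 62.8 on the array labelled wild type and 62.0 on the array labelled null, and 50.1% and 49.9% of probe sets lay above the floor. Over the 20905 probe sets above the floor on both arrays, the Pearson correlation of log2 intensities was 0.954, which is a correlation across probe sets and not across samples. There were no replicates.

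The targeted gene went against the labels. All 3 Cdk4 probe sets lay far below the floor on the array labelled wild type, at 1.19, 1.18 and 3.71, and were bright on the array labelled null, at 4945, 4506 and 6958. Cdk4 was thus at least 112-fold higher on the array labelled null. On that array its probe sets stood above 96.2% to 98.0% of all probe sets, and on the array labelled wild type above 2.19% to 9.57%. Directions below therefore follow the labels as given, and exchanging the labels would turn each of them.

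**Figure D1:**
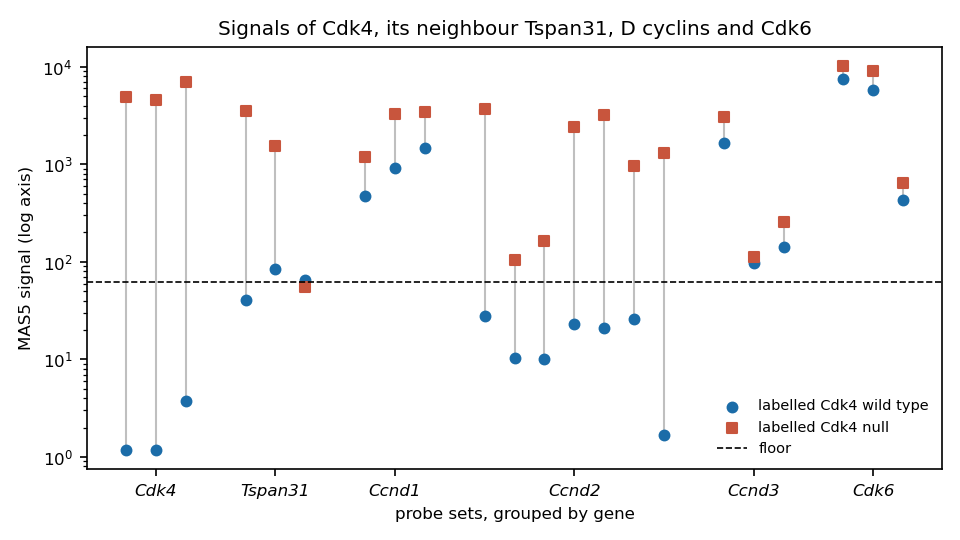
Intensity, on a log axis, of the probe sets of Cdk4, Tspan31, Ccnd1, Ccnd2, Ccnd3 and Cdk6 on the 2 arrays, with the floor of 62.2 as a line. All 3 Cdk4 probe sets lie below the floor on the array labelled wild type and between 4506 and 6958 on the array labelled null.

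The cultures differed in B-cell stage genes, in D-type cyclins, in immunoglobulin segments and in genes of some chromosomes. Vpreb1, which encodes part of the surrogate light chain of the pre-B cell receptor, was 35.7-fold higher on the array labelled null, and Ccnd2, which encodes cyclin D2, was at least 58.6-fold higher. Ly6d, a surface antigen of early B-lineage cells, was 14.9-fold lower on that array, and its relative Ly6k at least 94.7-fold lower. At 2-fold or more, 401 of the 9418 genes above the floor on both arrays were higher on the array labelled null and 308 were lower. Among genes above the floor on 1 array, 225 were at least 2-fold higher and 127 at least 2-fold lower. At 4-fold, 89 measured genes were higher and 67 lower. With shared probe sets left out, paired probe sets of a gene differed by less than 0.89 on the log2 scale in 95% of genes. This is under the 2-fold threshold of 1. The counts depend on the floor, with 833 higher and 779 lower at the 25th percentile of the signals and 118 and 83 at the 75th.

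Among the largest measured differences, Igfbp4, which encodes a binding protein of insulin-like growth factors, was 51.7-fold higher on the array labelled null. Pxdc1 was 36.2-fold, the kinase gene Stk26 23.5-fold and the ETS factor gene Etv5 22.9-fold higher, and Hsd17b11, a hydroxysteroid dehydrogenase of lipid droplets, stood at 63.4 against 1583. Lyz2, the lysozyme of myeloid cells, was 19.5-fold higher, Gimap1, a GTPase gene of lymphocytes, 17.6-fold, the immediate early factor gene Egr1 17.3-fold, Spred2, an inhibitor of ERK signalling, 17.3-fold, and Edaradd, the adaptor of the ectodysplasin receptor, 13.9-fold. On the array labelled wild type, Igfbp4, Pxdc1, Hsd17b11, Etv5, Lyz2, Egr1 and Edaradd lay between 63.4 and 71.1, near the floor. Their folds are thus close to bounds. The largest bounds were those of Rpl39l, a paralogue of a ribosomal protein gene, at least 132-fold, and of the metallothionein gene Mt1, at least 117-fold, beside Cdk4 itself. Tspan31, the next measured gene after Cdk4 on chromosome 10, was at least 56.8-fold higher, at 40.3 against 3531. Its other 2 probe sets read 84.6 against 1552 and 64.9 against 54.8. The latter was near the floor on one array and below it on the other, so its sign says little.

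Lower on the array labelled null were Fndc3c1 by 30.9-fold, Tmem87a by 18.6-fold, the potassium channel gene Kcnk1 by 17.9-fold and Cysltr1, a leukotriene receptor gene, by 13.5-fold. Hnrnpll, a splicing regulator of lymphocytes, was 12.2-fold lower, Spats2 10.1-fold, Nacc2 9.73-fold, and Bhlha15, a factor of secretory cells, 9.63-fold. Nxt2 was 9.57-fold, the phosphatase gene Ppm1l 9.55-fold and Mgst1, a microsomal glutathione transferase gene, 8.93-fold lower. On the array labelled null, Tmem87a, Cysltr1, Nacc2, Nxt2 and Ppm1l lay between 66.5 and 75.2, near the floor, so their folds are close to bounds. Bounds in this direction were at least 40.6-fold for Gja1, which encodes connexin 43, 40.3-fold for Tspan2, 39.3-fold for the forkhead factor gene Foxd1 and 27.2-fold for Dmrta2. With shared probe sets left out, 168 genes at 2-fold by their brightest remaining probe set had a second one above the floor. Of these, 160 had the same sign on it and 85 also reached 2-fold there. Genes named by a shared probe set, such as Igfbp4 and Mgst1, entered by other probe sets or not at all. Igll1, the other surrogate light chain gene, was 44.9-fold higher by a probe set that shares sequence with other transcripts. Its other probe set read 67.6 against 20.5, near the floor on one array and below it on the other. The difference of -0.12 without shared probe sets is therefore a bound, which neither bears out nor contradicts the rise.

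**Figure D2:**
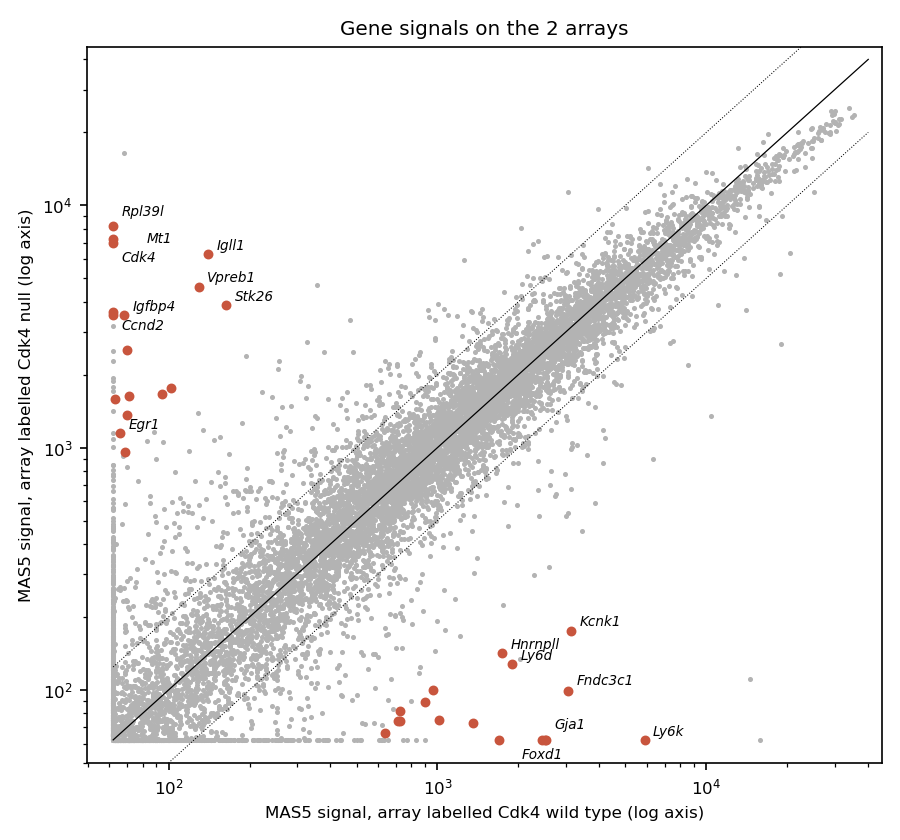
Intensity of each gene on the array labelled wild type (horizontal, log axis) against the array labelled null (vertical, log axis), with values under the floor drawn at it and the genes with the largest differences marked. Points off the diagonal by 2-fold or more are the 401 higher and 308 lower genes above the floor on both arrays and the bounds with 1 array at the floor.

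The kinase complex was higher on the array labelled null and the genes downstream of it did not stand apart. All 5 genes of the CDK4 complex list were above 0, with a median of 1.24 at percentile 100, but Cdk4 and Ccnd2 were at the floor on the array labelled wild type and could only lie above 0. Ccnd1 stood at 1472 against 3471 (2.36-fold), Ccnd3 at 1668 against 3030 (1.82-fold) and Cdk6, the sister kinase gene, named after its values were seen, at 7542 against 10120 (1.34-fold). The 7 CDK inhibitors had a median of 0.54 at percentile 98.3, with 6 above 0, and Cdkn1a, the inhibitor p21, stood at 62.9 against 240. CDK inhibitors were no longer apart with the floor at the 75th percentile of the signals (percentile 97.1) or with chromosome medians set to 0 (percentile 97.4). In contrast, 0 of the 38 measured DNA replication genes that E2F factors drive reached 2-fold, with a median of -0.05 at percentile 50.5. The same held for 0 of 34 mitosis genes, at -0.05 and percentile 49.9, and for 0 of 13 pocket protein and E2F factor genes, at -0.07 and percentile 24.97. Histone genes stood at percentile 90.6 with a median of 0.12, and 1 of 16 was higher and 1 lower by 2-fold, the latter H2bc21 at 424 against 123.

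Myc and its network did not differ by 2-fold, while Myc target genes of growth were slightly lower on the array labelled null. Myc stood at 15998 against 11857, and the 10 network factors had a median of 0.03 at percentile 60.9. The 38 Myc targets in growth and ribosome biogenesis had a median of -0.28 at percentile 0.19, with 33 below 0 and 1 lower by 2-fold. Cytosolic ribosomal protein genes had a median of -0.37 with 42 of 46 below 0, but this direction turned under quantile normalization, where the median was 0.02 at percentile 41.5. Myc targets kept theirs there, at -0.11 and percentile 0.75. The brightest of 10 bins of genes had a median difference of -0.14, and Actb and Gapdh, at -0.37 and -0.20, turned to 0.04 and 0.17 under quantile normalization.

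Pro-B and pre-B and germinal centre genes were higher on the array labelled null, while mature B-cell and pan-B genes did not stand apart. Markers of macrophages and of stromal cells were also higher on that array, both lists at percentile 100. The 17 pro-B and pre-B genes had a median of 0.29 at percentile 99.6, with 6 higher and 0 lower by 2-fold. They included Vpreb1, Igll1 by its shared probe set alone, Bst1, a surface enzyme of bone marrow precursors, at 63.7 against 399, and Cd93 at 1005 against 3929. The recombinase genes Rag1 and Rag2, both named after their values were seen, stood at 499 against 1531 and 118 against 373. Of 7 germinal centre genes, 3 were higher by 2-fold, among them the receptor gene S1pr2 at 113 against 589 and Bcl6, the repressor of that stage, at 124 against 284, with a list median of 0.67 at percentile 99.3. The 8 plasma cell genes had a median of 0.31 at percentile 98.2, with Derl3 at 179 against 660 and Irf4 in the other direction at 6590 against 3734. The 18 mature B-cell genes stood at percentile 97.4, and apart under 4 alternatives at percentiles from 97.96 to 99.85. Of them 6 were higher and 2 lower by 2-fold. The former included Tnfrsf13c, the BAFF receptor gene, at 187 against 1258, and the latter Cd40 at 226 against 38.3. Of the 18, 12 were above the floor on the array labelled wild type, and the others could only lie above 0. Cd40 and Itgb7 were at the floor on the array labelled null and could only lie below 0. Of 21 pan-B markers, 3 were higher and 0 lower by 2-fold at percentile 94.9, with Bank1 at 472 against 3367 and Cd37 at 2263 against 6926, and the list stood apart with the mean of probe sets (median 0.15, percentile 98.7). Plasma cell genes no longer stood apart under 5 alternatives, at percentiles from 87.3 to 94.97. Germinal centre genes no longer did with the floor at the 75th percentile of the signals, at percentile 92.2, and pro-B and pre-B genes no longer did with the floor at the 25th, where their median was 0.13.

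Immunoglobulin segments differed in both directions, with 2 of 11 measured genes higher and 4 lower by 2-fold and a median of -0.13 at percentile 29.1 that turned to 0.15 under quantile normalization and stood apart at -1.48 (percentile 0) over the 6 genes left with the floor at the 75th percentile of the signals. Igkv6-14, a kappa variable segment, was at 15877 on the array labelled wild type and 6.25 on the array labelled null, at least 255-fold lower there. Iglv1 stood at 14489 against 111 and Igkv8-30 at 18988 against 2680, whereas Ighv14-2, a heavy chain variable segment, stood at 286 against 1481. Of T cell receptor genes only 1 was above the floor on either array.

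Antigen presentation genes were higher on the array labelled null, together with markers of macrophages and stromal cells. All 10 measured MHC class II genes were above 0, with a median of 0.81 at percentile 99.97, and 1 was higher by 2-fold, H2-Ab1 at 568 against 1745. Of 11 MHC class I genes, 10 were above 0 and 5 higher by 2-fold, with a median of 0.72 at percentile 100, the peptide transporter gene Tap1 at 422 against 1190 and H2-D1 at 3945 against 9618. The macrophage, granulocyte and dendritic cell list had a median of 0.95 at percentile 100, with 11 of 11 above 0 and 5 higher by 2-fold, among them Lyz1 at 5.74 against 1890 and the complement gene C1qa at 1.27 against 139. Of the 11, 5 were above the floor on the array labelled wild type, and the others could only lie above 0. Stromal and endothelial markers had a median of 1.40 at percentile 100, with 9 of 15 higher by 2-fold, such as the collagen genes Col1a2 at 85.5 against 591 and Col3a1 at 33.6 against 286. Of the 15, 8 were at the floor on the array labelled wild type and could only lie above 0, and 3 were at the floor on the array labelled null and could only lie below it. The 4 members above the floor on both arrays were all above 0, with a median of 2.34. With the floor raised to the 75th percentile, 0 of the stromal members reached 2-fold and the list stood at percentile 91.8. T and NK markers stood at percentile 84.3 with 2 of 7 higher and 1 lower, the latter Cd6 at 429 against 108. Of erythroid genes only 2 were measured, with Car2 at 69.1 against 585. Interferon response genes stood at percentile 95.3, with 4 of 16 higher by 2-fold, and NF-kB targets at percentile 92.5, with 4 of 16 higher and 2 lower, among them Nfkb2, named after its values were seen, at 478 against 198. Interferon response genes stood apart with the pseudocount (median 0.49) and against unmatched random lists, and NF-kB targets without shared probe sets (median 0.73) and against unmatched random lists.

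**Figure D3:**
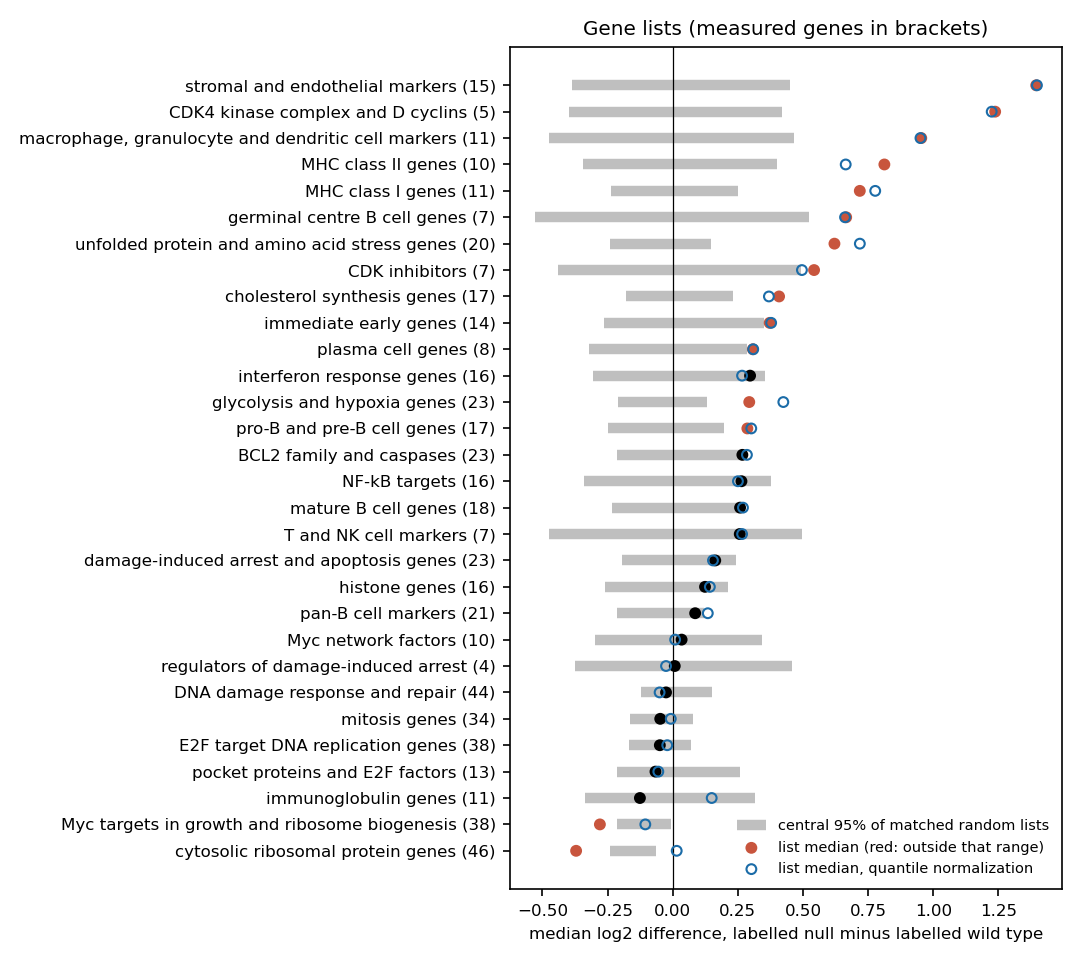
Median log2 difference (array labelled null minus array labelled wild type) of each gene list as a filled point, and under quantile normalization as an open point, beside the range that holds the middle 95% of 10000 random lists matched on signal. Of 30 lists, 13 lie above their range, 2 below it and 15 within, and ribosomal protein genes leave the lower side under quantile normalization.

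Stress, metabolic and immediate early genes were higher on the array labelled null, where the macrophage and stromal markers were higher too. The 20 unfolded protein and amino acid stress genes had a median of 0.62 at percentile 100, with 17 above 0 and 5 higher by 2-fold, led by the glutathione-degrading Chac1 at 60.1 against 560, Trib3 at 57.6 against 329 and asparagine synthetase, Asns, at 2359 against 7147. Of 23 glycolysis and hypoxia genes 18 were above 0, with a median of 0.29 at percentile 99.99 and the angiogenic factor gene Vegfa at 263 against 1470. The 17 cholesterol synthesis genes had a median of 0.41 at percentile 99.9, with 15 above 0 and Msmo1, a sterol oxidase gene, at 947 against 2216. Of 14 immediate early genes 3 were higher by 2-fold, with Egr1 joined by Fos at 34.5 against 589 and Ier2 at 254 against 2108, and a list median of 0.37 at percentile 98.1. Immediate early genes no longer stood apart with the floor at the 75th percentile of the signals or with chromosome medians set to 0, both at percentile 97.3.

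Damage response genes did not stand apart as lists, and cell death genes lay at the edge of the random range. Of 23 damage-induced arrest and apoptosis genes, 4 were higher and 0 lower by 2-fold at percentile 89.9, and they included the kinase gene Plk2 at 261 against 1118 and the BH3-only gene Pmaip1 at 67.6 against 232. The 4 measured regulators of damage-induced arrest had a median of 0.01 at percentile 45.5, with Bmi1 at 3577 against 2071 and Cdkn2a, which encodes the p16 and p19 proteins, at 741 against 1079. DNA damage response and repair genes had 0 of 44 members at 2-fold, with a median of -0.03 at percentile 27.9, Atm at 1842 against 1110 and the mismatch repair gene Msh6 at 3838 against 2240. Of 23 BCL2 family and caspase genes, 7 were higher and 1 lower by 2-fold with a median of 0.27 at percentile 97.3, and they stood apart under 5 alternatives, at percentiles from 97.76 to 99.13. The pore-forming Bak1 at 525 against 1353 and the initiator caspase gene Casp8 at 1469 against 3725, the latter named after its values were seen, were among them. So were Bcl2l1 at 208 against 498 and Cflar at 235 against 519, which oppose cell death and were also named after their values were seen. The list mixes genes that promote and genes that oppose cell death, so its median gives no direction for cell death.

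Genes of some chromosomes were shifted together. Chromosome 3 had the lowest median of the 20 chromosomes, at -0.44 over 521 genes (percentile 0), with 79.5% of them lower on the array labelled null. Chromosome 6 had the highest, at 0.24 over 523 genes (percentile 100), with 72.1% higher, and it carries Ccnd2 and Gimap1. Chromosome 5 stood at -0.15 (percentile 0) and chromosome 16 at -0.09 (percentile 0.015), but not along their whole length. Chromosomes 14 and 19 stood apart with medians of 0.08 and 0.05, but not along their whole length. Of 4 parts the last 2 lay within the random range, at 0.07 and 0.06 on chromosome 14 and 0.004 and -0.06 on chromosome 19. Chromosomes 2, 17 and 18 stood apart with medians of 0.04, 0.06 and 0.06. They lost that place without shared probe sets and under at least 1 other alternative each. The 4 parts of chromosome 17 had medians of -0.10, 0.17, 0.24 and -0.13. Divided into 4 parts of equal gene number, chromosome 3 had medians of -0.47, -0.37, -0.43 and -0.48, and chromosome 6 of 0.27, 0.20, 0.21 and 0.29. Those of chromosome 5 were -0.22, -0.17, -0.07 and -0.14, with the third within the random range, and those of chromosome 16 were 0.02, -0.03, -0.14 and -0.24, with the first 2 within it. Chromosome X as a whole did not stand apart, at -0.03, but the first of its 4 parts in gene order stood at 0.15 (percentile 99.3) and the last, from Bex1 to Erdr1, had a median of -1.11, with 44 of 77 genes lower by 2-fold. The 15 genes from Psmd10 to Tsr2 on X had the lowest median of any stretch of 15 genes, -2.52, and the highest was that from Lrrc61 to Gpnmb on chromosome 6, 1.36.

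**Figure D4:**
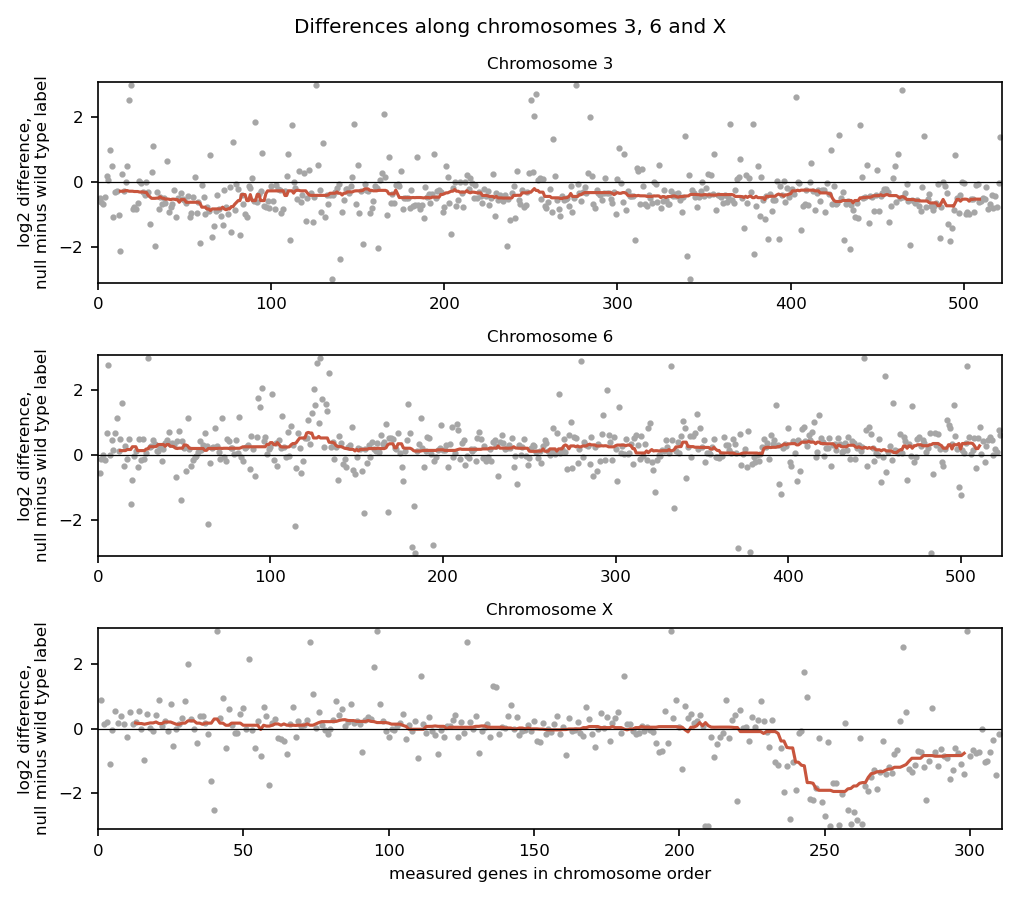
Log2 difference (array labelled null minus array labelled wild type) of measured genes in gene order along chromosomes 3, 6 and X, with values beyond 3 in either direction drawn at the edge, and the running median of 25 genes as a line. The running median stays below 0 along chromosome 3 and above 0 along chromosome 6, and the last of 4 parts of X has a median of -1.11.

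Of the sex-linked transcripts 1 was above the floor. Xist, the RNA that coats the inactive X chromosome, stood at 68.5 on the array labelled wild type and 16364 on the array labelled null, and 10 probe sets of the Y-linked genes Eif2s3y, Kdm5d, Uty and Usp9y were below the floor on both, at most at 15.8. The spiked controls also differed, since 18 of 18 hybridisation control probe sets were lower on the array labelled null, with a median of -0.88, and 24 of 24 poly-A control probe sets were higher, with a median of 0.43. The ratio of 3-prime to 5-prime probe sets, a measure of RNA quality, was 1.17 on both arrays for Actb and 0.80 and 0.81 for Gapdh.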

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

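Tests of exchanged labels, of probe sets outside the deleted part, of a loss on the Tspan31 side, of strain DNA around Cdk4 and of dim probe sets were chosen after the result was seen. Probe sets without a single gene name took no part in the comparison of genes. Among the 3085 of them above the floor on both arrays, 106 were higher on the array labelled null by 2-fold or more and 95 were lower, which singled them out as signal in data that the gene comparison did not use.

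Cdk4 was bright on the array labelled null. Probe sets outside the deleted part would explain that signal, but not 3 of 3 below the floor on the array labelled wild type. Those dark values are part of the observation that raised the question. Probe sets outside the deleted part thus stay open, if the dark values had a separate cause. Loss of a long piece of chromosome 10 on both sides of Cdk4 in that culture would raise the log2 differences of its neighbours, but the 20 nearest measured genes had a median of 0.18 and the 10 before Cdk4 a median of -0.07. DNA of another strain carried along with a targeted Cdk4 could crowd differences around it. Of the 100 nearest genes 12 reached 2-fold, against a median of 9 and a 95th percentile of 16 over all such windows. The count lay within the spread of windows, so it neither shows nor excludes such DNA. A loss that reaches from Cdk4 past Tspan31 stays open, since the 10 genes after Cdk4 had a median of 0.65 with 9 above 0, although 8 of them were above the floor on the array labelled wild type. An exchange of the 2 sample labels also stays open: the 3 of 3 probe sets dark on one array and bright on the other are the observation that raised it, and no other value tested it.

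Macrophage and stromal markers were higher on the array labelled null. Second lists, written before their values were seen, also stood higher: 14 macrophage genes had a median of 0.81 and 15 fibroblast genes a median of 1.14, but 9 and 12 of them were at the floor on the array labelled wild type and could only lie above 0. Noise of dim probe sets would leave these lists among random lists of like signal, but the lower of their percentiles was 99.94. The values are consistent with a few macrophages and fibroblasts in the culture labelled null, although genes above the floor on both arrays were divided: Mrc1 (107 against 177) and Cybb (321 against 352) were higher there and Ctss (5316 against 4244), Apoe (360 against 277) and Ctsl (657 against 359) lower, and of 3 fibroblast genes Pcolce (62.6 against 82.0) and Col6a2 (137 against 139) were higher and Fstl1 (326 against 143) lower. Transcription of such genes by the lymphoma cells themselves stays open, as does a difference tied to the genotype, which was not tested.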

How the results depend on the processing

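The alternative with chromosome medians set to 0 was chosen after the result was seen, and the others were planned. No paired analysis was possible because each group held 1 array. Values as deposited and a median difference set to 0 left the counts, list medians, chromosome medians and named genes on their side of the threshold. Among named genes other than Cdk4, 146 values moved by more than the probe set SD, 53 of them under the floor at the 75th percentile. The sign of 1 value reversed, that of the Igll1 bound given below. The T and NK list had too few members at that floor and gave no value. Genes near the floor are limited by low signal over background, and bounds depend on the floor by construction. For other changes the cause was not tested.

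Measured genes at 2-fold, higher and lower, numbered 833 and 779 with the floor at the 25th percentile, with 419 and 413 as bounds, and 118 and 83, with 83 and 38 as bounds, at the 75th. Bounds numbered 393 and 269 with the pseudocount. At 3-fold there were 171 higher and 122 lower, with 134 and 70 as bounds. The Cdk4 difference was 8.94 at the lower floor, 3.93 at the higher floor, 8.61 with the pseudocount, 6.43 as the mean of probe sets and 6.18 without shared probe sets.

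Under quantile normalization the ribosomal protein median reversed to 0.015, and BCL2 family and caspases (0.28) and mature B-cell genes (0.27) came to stand apart. At the lower floor BCL2 family and caspases (0.24) and chromosome 1 (0.027) came to stand apart, and pro-B and pre-B genes (0.13), chromosome 2 (0.0095) and chromosome 18 (0.045) no longer did. At the higher floor CDK inhibitors (0.51), germinal centre (0.36), plasma cell (0.16), stromal (0.38) and immediate early genes (0.36) and chromosome 18 (0.053) no longer stood apart, whereas BCL2 family and caspases (0.20), immunoglobulin genes (-1.48) and chromosome 7 (0.051) did. With the pseudocount, mature B-cell (0.58) and interferon genes (0.49) stood apart and chromosome 18 (0.062) did not.

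With the mean of probe sets, pan-B (0.15) and mature B-cell genes (0.30) and chromosome 10 (0.035) stood apart, and plasma cell genes (0.19) and chromosome 17 (0.018) did not. Without shared probe sets, BCL2 family and caspases (0.27) and NF-kB targets (0.73) stood apart. Plasma cell genes (0.31) and chromosomes 2 (0.031), 17 (0.036) and 18 (0.062) no longer did. Igll1 gave -0.12 there, a bound by a probe set near the floor, so its sign says little. Against unmatched random lists, BCL2 family and caspases (0.27), mature B-cell genes (0.26), NF-kB targets (0.26) and interferon genes (0.30) stood apart and plasma cell genes (0.31) did not. With chromosome medians set to 0, CDK inhibitors (0.46), plasma cell genes (0.19) and immediate early genes (0.32) no longer stood apart.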

Other observations

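The families below, and the tests of Xist silencing and of distal X, were chosen after the result was seen. Genes of the Gimap family, GTPases of lymphocyte survival that lie side by side on chromosome 6, were higher on the array labelled null. All 8 measured members were above 0, with a median of 1.65, and 7 were higher by 2-fold or more, or 6 under quantile normalization, but 5 of the 8 were at the floor on the array labelled wild type and could only lie above 0, so that 4 of the 7 differences are bounds. Gimap6 stood at 156 against 1107 and Gimap9 at 283 against 1167. The metallothionein gene Mt2 was 13.2-fold higher beside Mt1, while Mt3, at 16.9 against 64.2, gave a bound of only 1.03-fold.

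Genes that dampen ERK signalling and are induced by it were higher on the array labelled null, where Etv5, Egr1 and Spred2 had been among the largest differences. A second list of such genes, written before its values were seen, also held the receptor gene Plaur, at 78.6 against 109. It had 7 measured members of 16 on the array, with a median of 2.05 that is itself a bound. Of these members 5 were higher by 2-fold, 3 of them as bounds. The 4 members above the floor on both arrays were all above 0, with a median of 1.19. Examples were the phosphatase genes Dusp5 at 89.7 against 495 and Dusp4 at 2.22 against 291 and the inhibitor gene Spry2 at 13.2 against 317. A candidate explanation is stronger ERK output in the lymphoma cells of that culture, but the fibroblast and macrophage markers on the same array leave the cell of origin open.

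Genes of chromosomes 3 and 6 and of distal X were shifted together. A scaling trend would have faded under quantile normalization, which kept at least 97.2% of both medians, and a few strongly changed genes would leave most others near 0, but at least 72.1% of the genes lay in the direction of the shift. The shift was apart in 4 of 4 parts of chromosome 3 and in 4 of 4 parts of chromosome 6, which is consistent with a copy number difference along the whole of chromosome 3 and the whole of chromosome 6, and a loss in one culture or a gain in the other stay open, since no array of normal cells was compared. On the array labelled null, 1 of 4 parts of X stood lower and the first stood higher, at 0.15, so X was not lowered as a whole. Silencing of an X chromosome by Xist would lower all 4 parts only against a culture with more active X chromosomes. Their number in the culture labelled wild type is not known, so these values cannot decide on such silencing. For distal X, with its median of -1.11, a copy number difference and a regional change in expression cannot be told apart, since expression alone was measured.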
